A study of Mus musculus with 3 samples.

How the data were processed

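Gene expression was measured in cells sorted by flow cytometry from mouse yolk sac as positive for VE-cadherin, an endothelial adhesion protein, and CD45, a protein of the surface of blood cells. The labels assign 1 sample to a control group and 2 to a Tie-2-Etv2 group, in which an Etv2 transgene was switched on by Tie-2-Cre. Embryonic day 10.5 is stated for the control only. RNA of each sample was labelled with Cy3 and hybridised to its own 1-colour Agilent array of design 028005, and all 3 arrays lay on 1 slide read in 1 scan. Nothing in the labels says whether the 2 Tie-2-Etv2 samples came from separate litters or pools. The per-gene p-values therefore measure only the spread between these samples, which may be technical.

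Per the file headers and the submitters' processing notes, spot intensity values were extracted with Agilent Feature Extraction (version 10.7 in the notes, 10.7.3.1 in the headers), which subtracted background and replaced very dim values by a surrogate, with no scaling between arrays. The authors also deposited a table of log2 values whose scale and centring are not stated. Its differences between arrays matched those of the log2 processed signal, apart from 1 constant per array (0.756 and -0.0161), in 100% of 55668 probes within 0.01, and its values were centred on the median of the 3 arrays in every row; the column medians were 0, 0.136 and 0. Scale, centring and direction were therefore settled from the values, and the table served as an alternative.

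Each array held 59305 non-control spots for 55681 probes. Control spots and spots marked as outliers (168 to 174 per array) were left out, and no non-control spot was saturated. The log2 processed signal of replicate spots was averaged. Because under 50% of probes were well above background on each array, the 75th percentile subtracted from each array was taken over the 22764 probes well above background on all 3 arrays. Probes were tested where well above background on the control array or on both Tie-2-Etv2 arrays, which left 26214 probes of 19580 genes. Probe names were updated through a RefSeq table of assembly GRCm38.p6, used for names only: 26582 probes matched by accession, 2602 by symbol and 492 by synonym, while 26005 did not and kept the name in the files. Coordinates are those of the probes on build mm9, per the file headers. A gene was represented by its probe with the highest mean of both group means.

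Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 with data.table version 1.17.8, two-sided, with Benjamini-Hochberg adjustment over probes and a threshold of 0.05. The 1 residual degree of freedom came from the Tie-2-Etv2 pair, and the lone control was assumed to vary like it; moderation raised the total to 3.92. An exact permutation test of 1 array against 2 cannot give a p below 0.333. Genes at least 2-fold apart from the control in the same direction in both Tie-2-Etv2 arrays were also counted, with no test. In counts of list members 2-fold apart, values not above background were set to the array's lowest detected level where they lay under it, a choice made after the data were seen. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, and each list median was placed among those of 10000 random lists matched on expression in 20 bins. The estimated correlation came from the same 1 residual degree of freedom, which left that test almost no power. Not passing it therefore says little about a list. Camera's p at the preset correlation and the random-list percentile compare genes with genes. They do not measure spread between samples, so a small value says nothing about replication. List members without a tested probe were left out. Lists with fewer than 5 tested members received no test. A gene well above background in 1 group and on no array of the other was given a bound: the bright group's mean over, per dim array, the higher of the dim probe's own value and the lowest value among probes well above background. Bounds hold for this processing only, and some alternatives gave smaller differences.

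The groups, tests, 18 gene lists and rule for named genes were fixed before the data were examined. The rule named Etv2, Tek, Cdh5 and Ptprc; the 10 highest and 10 lowest genes passing the test and well above background on all 3 arrays; the 5 largest bounds in each direction; and up to 4 members of each list that passed, or the 2 members with the largest differences where none did. As no gene passed, the same rule gave the 10 highest and lowest places to the genes with the largest value of the smaller of their 2 differences from control. Of the genes with the largest bounds, 1 that the rule picked is not used here. Other genes named in the text were chosen after their values were seen.

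The fit was tested on simulated data: in 20 simulations over 26214 probes with the variances fitted here, 200 probes were given log2 changes of 1, 2 or 4. At adjusted p 0.05 the fit called 0% of the changed probes at each of the 3 sizes and on average 0.3 unchanged probes. The rule of a 2-fold difference in both arrays took 36.4%, 93.3% and 99.5% of them, and also 3.79% of unchanged probes, or 986 per simulation. Camera called a list of 30 probes shifted by 1 in 20 of 20 simulations, and 1 of 380 unchanged lists; the simulated probes were independent, which real genes of a list are not.

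Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the percentile over all probes, the authors' log2 table, no filter on dim probes, a filter on all 3 arrays, the mean of a gene's probes, eBayes with a trend or robust, other thresholds, and leaving out each Tie-2-Etv2 array. Scaling on spike-in probes and leaving out spots in bright patches (a 5 by 5 window whose median exceeds the mean of the other 2 arrays by more than 1 on the log2 scale) were added after the data were seen, as was counting all genes with dim values at the array's lowest detected level. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.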

Results

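VE-cadherin+ CD45+ yolk sac cells, a fraction that carries both an endothelial and a blood cell surface protein, were profiled on 1 control array and 2 Tie-2-Etv2 arrays. Tie-2-Etv2 embryos carry a transgene for Etv2, an ETS transcription factor of early endothelial and blood development, switched on by a Cre driven from the Tie-2 (Tek) promoter. The series asks how expression in yolk sac hematopoietic precursors differs when Etv2 is kept on. Well above background were 25464 probes on the control array, 24218 on Tie-2-Etv2 replicate 1 and 27018 on replicate 2. The replicate 1 array was dimmer: the 75th percentile of detected probes was 1199 intensity units, against 2073 for the control and 2092 for replicate 2. Levels below are log2 signal relative to that percentile, and the number of arrays limits their precision.

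Etv2 was 14.1-fold higher in the Tie-2-Etv2 arrays (21.5-fold on replicate 1, 9.30-fold on replicate 2), at -1.01 ± 0.85 (SD, n = 2) against -4.84 in the control array. Cdh5, which encodes VE-cadherin, was 11.6-fold higher (22.1-fold and 6.05-fold), and Tek, the receptor gene whose promoter drives Cre, was 5.76-fold higher. Ptprc, which encodes CD45, was 0.46 lower on the log2 scale, with a standard error of 0.32. The Etv2 probe lies at chromosome 7, 31419633 to 31419692 (mm9), starting at base 655 of its transcript. A second Etv2 probe, at 31418776 to 31418835, gave a log2 difference of 2.32 ± 0.44 (SE) against 3.82 ± 0.62 for the first. Whether either probe detects the transgene's transcript is not stated by the labels. In limma's test over all probes, Etv2 had an adjusted p of 0.237, Tek 0.289, Cdh5 0.328 and Ptprc 0.775, so none passed.

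**Figure D1:**
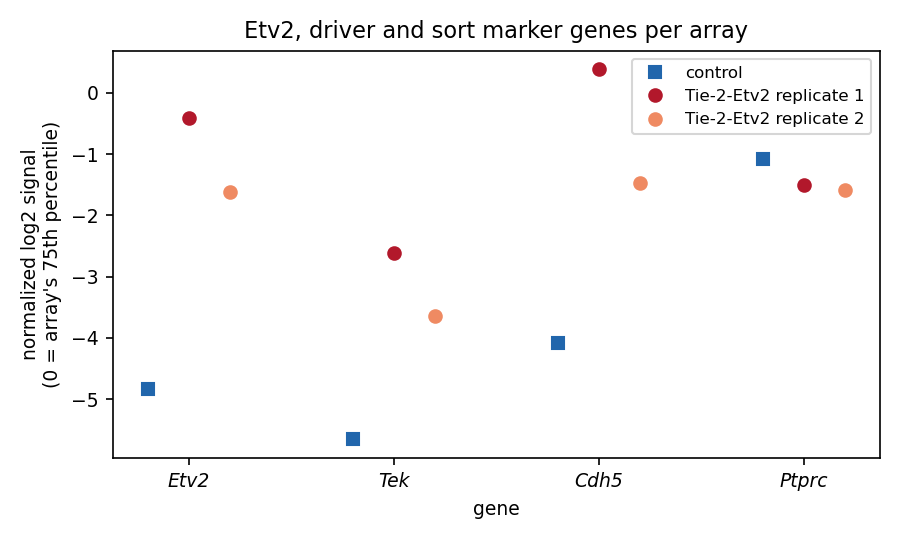
Normalized log2 signal (vertical axis, 0 is the array's 75th percentile) of Etv2, the driver gene and both sort marker genes, with 1 point per array. Etv2, Tek and Cdh5 lie higher on both Tie-2-Etv2 arrays than on the control array, while Ptprc differs by -0.46.

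Among genes detected on all 3 arrays, Dysf, which encodes the membrane repair protein dysferlin, was 52.8-fold higher in the mean of the Tie-2-Etv2 arrays, with log2 differences of 6.81 on replicate 1 and 4.64 on replicate 2. S100a8 and S100a9, which encode the calprotectin subunits of myeloid cells, were 28.6-fold and 17.4-fold higher. Hid1, Hapln1, Dhrs2, Tspan18, Mrgpra6 and Mrgpra2b completed the highest 10 together with Etv2, at log2 differences of 5.10, 4.66, 4.57, 4.09, 3.83 and 3.83. Among the lowest 10, Adgre1, which encodes the macrophage antigen F4/80, was 37.0-fold lower (70.2-fold on replicate 1, 19.5-fold on replicate 2). Col1a1, a fibrillar collagen gene, was 25.8-fold lower, and Slc40a1, the iron exporter ferroportin, was 23.8-fold lower (45.0-fold and 12.6-fold). Ifi207, Clec4a1, Timp2, Ccl7, Cd83, Gas6 and Pdlim4 differed by -5.16, -5.01, -4.80, -4.64, -4.53, -4.29 and -4.18. Mrgpra6 and Mrgpra2b belong to a family of near-identical genes, as Ifi207 does, so their probes may not tell the copies apart. Of the family of Ifi207, Ifi203 was 42.2-fold higher on replicate 1 and 5.53-fold on replicate 2. Ifi202b had a level of 0.965 on the control array. Its log2 difference was -0.38 on replicate 2 and a measured -9.25 on replicate 1, where it was not above background. The cause of this gap between the replicates was not tested. Except for Col1a1, each of the highest and lowest 10 lay further from the control on replicate 1 than on replicate 2, Hid1 at 6.15 and 4.05 and Ifi207 at -6.29 and -4.02, and the plot of these genes shows both values of each.

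No gene passed an adjusted p of 0.05 in limma's test; the smallest adjusted p was 0.200, and 2110 genes had an unadjusted p under 0.05, 864 higher and 1246 lower. By their measured values, dim ones included, 767 genes were 2-fold or more higher than the control in both Tie-2-Etv2 arrays and 1300 lower, 2067 in all. With values not above background at the array's lowest detected level the counts were 620 and 1009, and with probes detected on all 3 arrays 502 and 593. The main filter takes a gene detected on the control array alone but otherwise asks for both Tie-2-Etv2 arrays, which favours lower genes. A filter of that form also gave more lower than higher genes with replicate 1 (1067 and 879) or replicate 2 (289 and 130) in the control's place. Over probes the count was 2640, where simulated unchanged probes gave 986. The simulation had independent probes whose spread did not depend on intensity, so its count is a rough guide only. Of the genes 2-fold apart, 339 had more than 1 tested probe, and 23 of these had a probe of opposite sign. Replicate 1 taken alone was 2-fold apart from the control in 3978 genes and replicate 2 in 2529. With normexp background correction 614 genes passed (248 higher, 366 lower) and 803 were 2-fold apart; with no filter on dim probes 440 passed (130 higher, 310 lower). With the replicate 1 array set against the other pair, under a filter of the same form, 1946 genes were 2-fold apart and 2133 had an unadjusted p under 0.05, and with replicate 2 set against them 419 and 316.

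**Figure D2:**
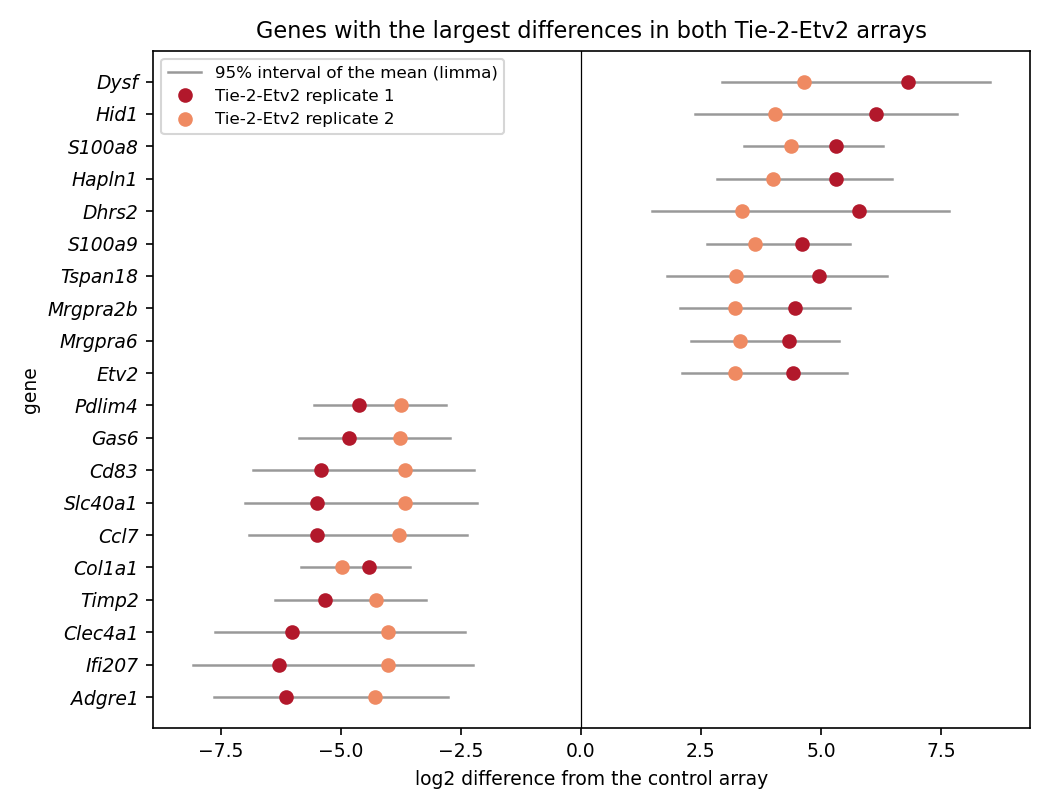
Log2 difference from the control array (horizontal axis) of the 10 highest and 10 lowest genes detected on all arrays, with 1 point per Tie-2-Etv2 array and a line for limma's 95% interval of the mean difference. Dysf is highest at 5.72 and Adgre1 lowest at -5.21 on average; none passed the adjusted test.

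Some genes were well above background in 1 group only, and their bounds below are means over both Tie-2-Etv2 arrays. The bounds hold for the main processing only. Sox18, an endothelial transcription factor gene, was at least 108-fold higher in the mean of the Tie-2-Etv2 arrays, at least 213-fold on replicate 1 and 55.1-fold on replicate 2. It was followed by Cda, Adam7, Lax1 and Kcnj16 at bounds of at least 17.9-fold, 17.8-fold, 14.7-fold and 14.4-fold, and on replicate 2 alone the bounds of these 4 were 6.55-fold to 11.4-fold. Over the alternatives run, the smallest log2 differences were 4.49 for Sox18, 2.12 for Cda, 2.13 for Adam7, 1.96 for Lax1 and 1.97 for Kcnj16. In the other direction Slitrk4 was at least 24.4-fold lower, St6gal1 20.6-fold, Olfr1250 19.6-fold and Akr1cl 17.1-fold. Over the alternatives run they shrank to log2 differences of -2.375, -2.08, -2.18 and -2.19. The control spots of Slitrk4, Olfr1250 and Akr1cl each lay within 2 spots of another probe that was bright on the control array alone, and St6gal1 lay 13.6 spots from the nearest. None of these genes passed the adjusted test.

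Endothelial genes were higher as a group: 21 of 37 tested members were at least 2-fold higher in both Tie-2-Etv2 arrays and 4 at least 2-fold lower, with a median log2 difference of 1.82 (2.51 on replicate 1, 1.16 on replicate 2). Besides Sox18, Flt4, a lymphatic and endothelial receptor gene, was at least 6.01-fold higher, 3.1-fold on replicate 2. The smallest log2 difference of Flt4 over the alternatives run was 1.44. Lyve1, Nrp1 and Vwf, also endothelial genes, had log2 differences of -3.37 (-3.98 on replicate 1, -2.76 on replicate 2), -2.02 and -1.23. Stab2 was at -2.94 on replicate 2 and at least 12.1-fold lower on replicate 1, where it was not above background. Genes reported as Etv2 targets had a median of 1.58, with 13 of 22 members 2-fold higher in both arrays, among them Flt4 and Notch4 (12.0-fold, 21.7-fold on replicate 1 and 6.69-fold on replicate 2); 10 of the 22 are also in the endothelial list. Kdr, in both lists, gave 0.50 with its chosen probe and 3.38 with its other probe. Camera gave adjusted p of 2.07e-06 for the endothelial and 2.32e-08 for the target list, and an adjusted p of 0.549 for each with an estimated correlation. That estimate rests on 1 residual degree of freedom here and for the lists below, so the test with it could hardly pass. Camera's p-values at the preset correlation, here and below, measure spread between genes and not between samples. Adjusted over the list alone, 2 endothelial members passed (Sox18 higher, Stab2 lower) and 9 target members, all higher; adjusted over all genes, 0 did. The ETS family list did not pass (median 0.13, mean -0.01, adjusted p = 0.438): Etv2 was at 3.82, and Etv1 was at -2.95 on replicate 2 and not above background on replicate 1, at least 25.6-fold lower.

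Macrophage genes were the furthest below the control, with 22 of 30 members at least 2-fold lower in both arrays and a median of -3.19 (-2.92 with genes known in 1 group only at their bounds). Adgre1 had a log2 difference of -5.21, and Slc11a1 was at -3.31 on replicate 2 and at least 139-fold lower on replicate 1, where it was not above background, whereas Itgam, Lyz1 and Lyz2 were at 1.04, 1.40 and 1.08. Granulocyte and mast cell genes had a median of 1.18, with 7 of 15 members 2-fold higher, S100a8 and S100a9 leading. Of the 24 genes fixed for this list, Ms4a2, Mcpt8, Cma1, Mcpt4, Tpsab1, Prg2, Epx, Fcer1a and Ngp were not tested. The mast cell genes Cpa3, Tpsb2 and Hdc were at 3.915, -0.27 and 0.0078 on replicate 1. On replicate 2 they were at 2.707, -0.074 and 1.02. Hematopoietic progenitor genes had a median of 0.75, with 8 of 31 members 2-fold higher and 1 lower. Itga2b, which encodes CD41, was 4.90-fold higher and Hlf 4.55-fold lower. Over the alternatives run the log2 difference was 2.119 to 2.466 for Itga2b and -2.285 to -0.8544 for Hlf. Camera's adjusted p was 4.25e-12 for macrophage, 2.14e-06 for granulocyte and mast cell and 1.66e-05 for progenitor genes, and an adjusted p of 0.549 for each with an estimated correlation. Adjusted over the list alone, 9, 5 and 2 members passed, and 0 over all genes. The granulocyte and mast cell median was 0.60 with normexp background correction and 0.47 with no filter on dim probes. Beside these groups the visceral endoderm list had a median of -2.59 and the mesenchyme list -1.88.

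Erythroid genes had a median of -1.38 (-1.83 on replicate 1, -0.88 on replicate 2), with 10 of 27 members at least 2-fold lower in both arrays and 1 higher. Rhd was at least 3.03-fold lower, and Car2, which encodes carbonic anhydrase 2, was 7.24-fold higher (11.3-fold on replicate 1, 4.63-fold on replicate 2). The bound of Rhd holds for the main processing only, and its smallest log2 difference over the alternatives run was -0.26. The embryonic globin genes Hbb-y, Hbb-bh1 and Hba-x were at -2.11, -2.14 and -2.21 and the adult Hba-a1 and Hba-a2 at -2.09 and -1.93, while the adult Hbb-bt and Hbb-b2 were at 3.93 and 2.30 on replicate 1 and 0.64 and -0.18 on replicate 2. Camera's adjusted p was 1.67e-06, with an adjusted p of 0.549 with an estimated correlation, and 13 members passed adjusted over the list alone, 12 lower and 1, Car2, higher. Setting genes known in 1 group only to their bounds moved the median to -0.85, and normexp background correction gave -0.26. Megakaryocyte genes did not pass (median 0.52, with 0.13 on replicate 1 and 0.92 on replicate 2, adjusted p = 0.143), with 6 of 20 members 2-fold higher in both arrays and 2 lower; 7 passed adjusted over the list alone, 5 higher and 2 lower. Mmrn1 and Clec1b were 11.2-fold and 8.92-fold higher (Clec1b 14.1-fold on replicate 1, 5.64-fold on replicate 2). Pf4, a platelet chemokine gene that is also in the macrophage list, was at -1.76. Lymphoid genes had a median of -0.35, with -0.30 on replicate 1 and -0.68 on replicate 2 (adjusted p = 0.0126, and 0.549 with an estimated correlation), with Blnk and Flt3 at -2.92 and -2.30 and 3 of 11 members passing adjusted over the list alone. The lymphoid median was 0.14 with normexp background correction and 0.08 without the filter on dim probes. Of the 22 genes fixed for the lymphoid list only these 11 were tested.

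Genes of other yolk sac cells were also lower. Of 29 visceral endoderm genes, 20 were at least 2-fold lower in both arrays and 1 higher, Sox17, which is also in the endothelial list; Foxa2 was at -1.31 on replicate 2 and at least 8.67-fold lower on replicate 1, where it was not above background. The list's median was -3.94 on replicate 1 and -1.18 on replicate 2, and 0 members passed adjusted over the list alone. Of 14 mesenchyme and mesothelium genes, 7 were 2-fold lower in both arrays, with a median of -1.88; the median was -1.35 with genes known in 1 group only at their bounds and -0.54 with normexp. Lum was at least 15.1-fold lower, Col1a1 25.8-fold lower, and 9 members passed adjusted over the list alone, 8 lower and 1, Twist1, higher. Lum shrank to a log2 difference of -1.74 over the alternatives run. Of the 23 genes fixed for the mesenchyme and mesothelium list only these 14 were tested. Camera's adjusted p was 2.32e-08 for visceral endoderm and 8.30e-08 for mesenchyme, and an adjusted p of 0.549 for each with an estimated correlation.

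Immediate early genes, which also respond to cell dissociation, had a median of -1.24 (-1.29 on replicate 1, -0.78 on replicate 2), with 9 of 21 members 2-fold lower and Atf3 at -4.43 (-5.86 on replicate 1, -3.01 on replicate 2). Ccn1 was at -2.81 on replicate 2 and at least 18.0-fold lower on replicate 1, where it was not above background. Interferon response genes had a median of -0.58 (-0.32 on replicate 1, -0.93 on replicate 2), with 5 of 15 members 2-fold lower. Ifit3 was at least 2.86-fold lower and Oas2, not above background on replicate 1, was at -3.22 on replicate 2. The bound of Ifit3 holds for the main processing only, and its smallest log2 difference over the alternatives run was -0.44. Camera's adjusted p was 6.41e-06 and 0.000410, and an adjusted p of 0.549 for each with an estimated correlation; 0 and 5 members passed adjusted over the list alone. Cell cycle genes had a median of 0.06 with 0 of 30 members 2-fold apart, and Gins2 and Cdc20 at -0.59 and 0.38 (adjusted p = 0.983). The p53, hypoxia and Notch lists did not pass, at medians of -0.21, -0.10 and 0.80 and adjusted p of 0.143, 0.438 and 0.123. The Notch median was 1.02 on replicate 1, 0.29 on replicate 2 and 0.19 with no filter on dim probes. The leading members of these 3 lists were Gdf15 (-2.54 on replicate 2, not above background on replicate 1) and Pmaip1 (-3.12 on replicate 1, -1.06 on replicate 2), Adm (at least 1.74-fold lower) and Pfkfb4 (-1.72), and Notch4 (4.44 and 2.74) and Nrarp (3.78 and 2.33). Adm shrank to a log2 difference of -0.096 over the alternatives run. Of the sex-linked genes 3 were tested, with Xist at -0.55.

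**Figure D3:**
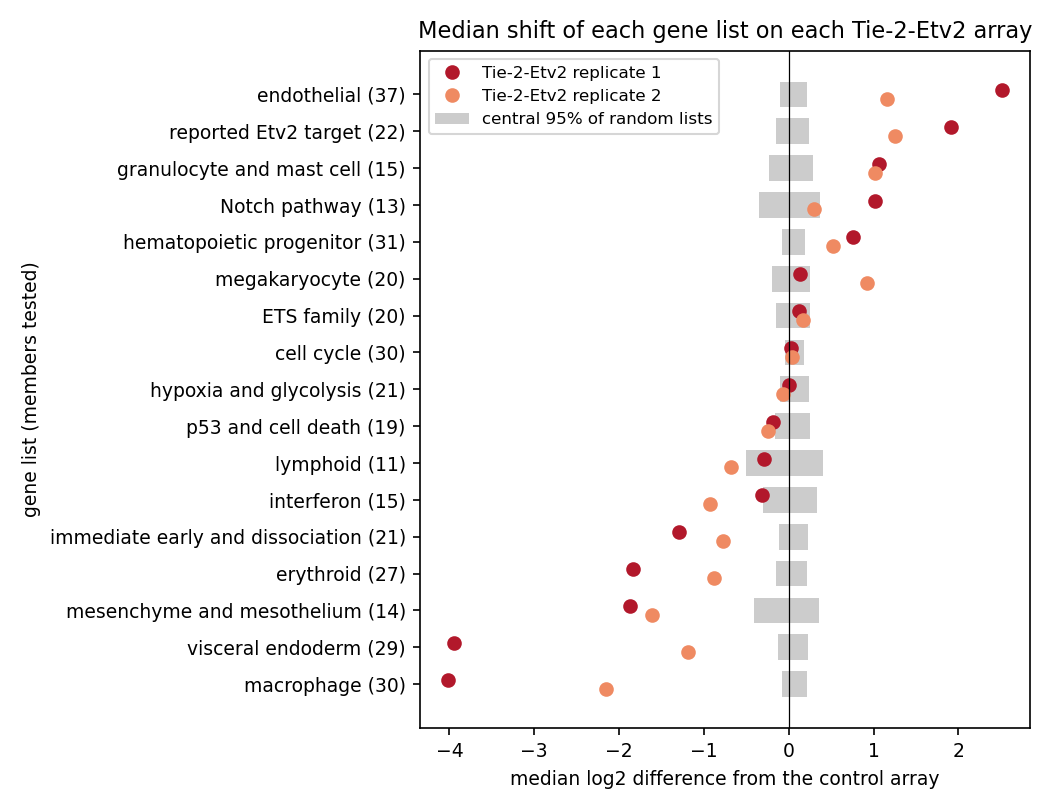
Median log2 difference from the control array (horizontal axis) of each gene list with at least 5 tested members, with 1 point per Tie-2-Etv2 array and a grey bar for the central 95% of 10000 random lists matched on expression. The endothelial median is 2.51 on replicate 1 and 1.16 on replicate 2, and the macrophage median is -4.02 and -2.15.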

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

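Scaling on spike-in probes was chosen only after the result was seen. The spike-in probes, which the comparisons did not use, were brighter relative to the 75th percentile on the Tie-2-Etv2 replicate 1 array than on the control array. The median difference was 0.199 on the log2 scale, and 8 of 8 detected spike-in probes were higher. On the replicate 2 array the median difference was -0.0269, with 3 of 8 higher. Scaling on these probes left the Etv2 difference at 3.74.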

How the results depend on the processing

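Spike-in scaling, leaving out bright patches and setting values not above background to the array's lowest detected level were chosen after the data were seen; the other alternatives were planned. Etv2 was higher under all alternatives run (2.97 to 4.42; adjusted p 1.96e-08 to 0.390). It passed with normexp (2.97) and with no filter on dim probes (3.82). The number of genes passing was 0 except with normexp (614) and no filter (440), where limma's prior degrees of freedom were infinite and 20.1 against 2.92; the cause was not tested. Of 61 genes picked by the rule for named genes 1, Eif2s3y, changed sign. Genes 2-fold apart in both arrays (2067; 767 higher, 1300 lower) numbered 803 with normexp (312 and 491), 1095 with probes detected on all 3 arrays (502 and 593, from fewer genes) and 645 at a log2 difference of 2 (183 and 462). With values not above background at the array's lowest detected level they numbered 1629 (620 and 1009), and with no filter 1317 were higher. With 1 Tie-2-Etv2 array left out, which leaves no residual degree of freedom and so no test, the count was 2529 to 3978 (895 to 1774 higher, 1634 to 2204 lower), since 1 array then has to pass. With an estimated correlation the lists endothelial (1.82), reported Etv2 target (1.58), hematopoietic progenitor (0.75), erythroid (-1.38), macrophage (-3.19), granulocyte (1.18), lymphoid (-0.35), visceral endoderm (-2.59), mesenchyme (-1.88), immediate early (-1.24) and interferon (-0.58) no longer passed. That estimate came from 1 residual degree of freedom, which leaves almost no power, so this outcome decides little. Megakaryocyte genes passed with normexp (0.57), probes detected on all 3 arrays (0.93) and the random-list percentile (0.52). The Notch list passed with normexp (0.55), spike-in scaling (0.71) and the percentile (0.80), and the p53 list with the percentile (-0.21). The lymphoid list did not pass by the percentile (-0.35) and changed sign with normexp (0.14) and no filter (0.076). The ETS list changed sign with the authors' table (-0.050), the cell cycle list with spike-in scaling (-0.019) and the mean of a gene's probes (-0.021), and Eif2s3y with normexp (0.0031) and without replicate 2 (0.29); the cause was not tested for any of these. Leaving out each Tie-2-Etv2 array gave ETS 0.12 to 0.17, progenitor 0.52 to 0.76, granulocyte 1.02 to 1.06, lymphoid -0.68 to -0.30, mesenchyme -1.87 to -1.62, cell cycle 0.029 to 0.038, immediate early -1.29 to -0.78, megakaryocyte 0.13 to 0.92, Notch 0.29 to 1.02 and hypoxia -0.066 to 0.0071. No scaling moved the median of all genes by over 0.1. The slide as a block was not run, since all arrays share 1 slide. No paired analysis was possible because the control has 1 array. Signal over background limits the bounds, and 503 and 632 genes were detected in the Tie-2-Etv2 or control group alone.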

Other observations

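The tests of spot position, of spread within the visceral endoderm list, of distance between replicates and of the choice of odd array were chosen only after the results were seen. Some genes in none of the fixed lists are given here, and none passed limma's adjusted test. They were chosen after their values were seen, except Ccl7, which the rule for named genes picked. The stefin A family genes Stfa1, Stfa3 and Cstdc5 were 7.13-fold, 8.32-fold and 8.57-fold higher in the Tie-2-Etv2 arrays, close in both arrays, and whether their probes tell such near-identical copies apart was not tested. The chemokine genes Ccl2, Ccl7 and Ccl12 were 39.0-fold, 45.0-fold and 31.2-fold lower on replicate 1 and 8.03-fold, 13.7-fold and 8.99-fold lower on replicate 2.

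Of the probes bright on the control array and on neither Tie-2-Etv2 array, 30 exceeded a normalized level of -4. Their median distance to the nearest other such spot was 1.41 spots, against 22.8 (15.9 to 30.1) for random probes (permutation p = 0.0001, the smallest these permutations can give). Levels of -4.5 and -5 gave 1.41 as well, and with no level required the median was 3.61 against 4.12. This argues against expression in the control cells as the whole cause, and bright patches on the array's surface are a candidate explanation for the 18 probes with another within 2 spots, Slitrk4, Olfr1250 and Akr1cl among them. The window rule for patches holds 10 control spots, with Slitrk4 but not Olfr1250 or Akr1cl among them, and replicate 1 had 73 probes bright on it alone, 51 of them within 2 spots of another, so expression stays open for the 12 isolated probes, Lum, Clec10a and St6gal1 among them, and is not excluded for any single gene.

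Visceral endoderm genes were lower on both Tie-2-Etv2 arrays, and on replicate 2, as bright as the control array, the list median was -1.18 against -0.12 to 0.21 for random lists, which argues against the dimmer replicate 1 array as the cause. Less visceral endoderm RNA in the Tie-2-Etv2 libraries would give the members 1 shared ratio per array only if no other sorted cells expressed them, which was not tested. Among 22 detected members the SD was 0.283 on replicate 2 (random lists 0.290 to 1.05) but 1.44 on replicate 1 (0.438 to 1.63). The random lists were matched on level and not on the size of the shift. The test was first scored on replicate 2 alone, where the SD lay under the random range, and was rescored on both arrays after the replicate 1 SD had been seen; the median absolute deviation, also tried, gave percentiles of 0.02 and 97.7. On replicate 1 Gata4 and Trf were at 0.30 and 0.0074, and the other detected members ranged from -2.03 (Krt18) to -4.70 (Rbp4). Because the replicate 1 SD lay within the random range, the test did not decide. Less endoderm RNA and lower expression of these genes in the sorted cells cannot be told apart. Afp and Ttr, abundant endoderm transcripts, were at -4.07 and -4.64 on replicate 1 and -1.25 and -1.33 on replicate 2. The 22 detected members were well above background on the control array and on both Tie-2-Etv2 arrays. Their RNA was therefore present after the sort for VE-cadherin and CD45. Whether it came from endoderm cells that passed the sort was not tested. A difference in embryo stage or an effect of the transgene stays open, untested.

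Replicate 1 lay further from the control than replicate 2. A dimmer array would lower its signals, but 32 endothelial members detected on all arrays were higher on replicate 1 by a median of 1.19 (random lists -0.14 to 0.22). If replicate 2 were 1 mixture of control-like and replicate 1-like RNA, every list would lie the same share of the way. On the linear scale the share was 27.9% for 27 endothelial, 60.9% for 20 visceral endoderm, 85.8% for 23 macrophage and 88.9% for 14 erythroid members. Endothelial and macrophage members differed by 57.9 percentage points (permutation p = 5e-05, 100000 resamples). The permutation treats genes as independent, so its p measures spread between genes and not between samples. The unequal shares argue against 1 such mixture. The part of the dimmer array is not decided, and a difference in stage, litter or transgene level between the samples stays open, untested.

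Of the 3 choices of the array set against the remaining pair, each with probes well above background on that array or on both others, 1, the real one, gave as many as 2067 genes 2-fold apart, and the highest other, replicate 1, gave 1946. With probes well above background on all 3 arrays the real choice gave 1095 and replicate 1 gave 927. With 3 choices the share cannot be under 0.05.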
